A study of Mus musculus with 10 samples.

How the data were processed

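Nuclear RNA of the mouse hippocampus was measured by droplet-based single-nucleus RNA sequencing. The mice carried conditional alleles of Fos, Fosb and Junb, 3 genes of the AP-1 transcription factor family. Per the labels' protocols, an adeno-associated virus coding for Cre recombinase or for an inactive form of it (deltaCre), each joined to a green fluorescent protein, was injected into area CA1 of the hippocampus on 1 side of the brain, and the other side was left without virus. All mice received kainic acid, an agonist of glutamate receptors that causes strong neuronal firing, for 4 h. CA1 was then dissected from slices, tissue was homogenised, and nuclei were collected on a density gradient. The 10 libraries fell into 4 groups, read from the titles and virus labels: Cre-injected (n = 3), its contralateral side (n = 3), deltaCre-injected (n = 2) and its contralateral side (n = 2). The titles of the 3 controls of Cre also hold the letters WT, and what these mean for mice with conditional alleles is not given in the sources used here. They were read as the side without virus, and a difference in genotype between them and the Cre-injected libraries would enter every comparison of both. Libraries without kainic acid were not analysed here, so no value describes an induction. One contralateral library carried a virus tag that pointed to the first pair while its title pointed to the second, and the number of its title was used.

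The files held unnormalised counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors deposited as sparse matrices with whole numbers only. Per the submitters' processing notes these counts came from Cell Ranger on the mouse build mm10. The Cell Ranger version, the settings for intronic reads and the barcode calling are not given in the sources used here. No cell annotation was used. Of the 28692 gene entries, 28339 matched GENCODE vM21 by Ensembl ID, and coordinates are given from that annotation on mm10 (1-based). A further entry held WPRE, a regulatory element of the viral constructs, and was used as a marker of transduction.

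Barcodes with at least 500 genes and at most 5% mitochondrial counts were kept as nuclei. This removed 14646 of 98548 barcodes for few genes and 5 others for mitochondrial counts. Doublets were scored per library with Scrublet as included in scanpy 1.11.5. The automatic threshold marked under 0.5% of barcodes in 5 libraries, so the highest scores were removed at a rate of 0.8% per 1000 barcodes. That rate was chosen after the automatic threshold had been seen, and it removed 7850 barcodes and left 76047 nuclei. Counts were log-normalised, 2000 variable genes and 30 principal components were used, a graph of 15 neighbours was built without batch correction, and Leiden clustering (leidenalg 0.10.2, seed 0) was run at resolution 1. A cluster was named after a cell class if at least 3 of the class's fixed markers were detected, and a cluster with markers of more than 1 class was clustered again. The thresholds of this naming were set after the clusters had been seen. Clusters with fewer markers, markers of another lineage, few UMIs for their library, under 100 nuclei or leading genes against the name stayed unnamed. They held 15.5% of nuclei of the Cre contralateral group, 6.09% of the Cre-injected group, 15.0% of the deltaCre contralateral group and 2.95% of the deltaCre-injected group. Because names were rebuilt from markers, shares of classes depend on them, and shares of glial classes are also given with the unnamed clusters that held their markers, counts added after the data had been seen. Ratios of genes with 1 to 3 UMIs in a group are ratios of pooled counts over pooled totals, with exact conditional binomial intervals.

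Counts were summed per library and class where a library had at least 20 nuclei of the class. Sums were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, genes kept by filterByExpr), with 1 mean per group and all groups of the class in the fit. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The adjusted p-values of genes in the texts are from this test unless another tool is named. Levels are counts scaled to a common library total with TMM factors (CPM), given as mean ± SD over libraries, and fold changes are log2 values of the edgeR fit. The libraries of a group were taken as independent replicates, which the labels state only as replicate numbers, and the number of mice per library is not given in the sources used here. Gene lists were tested on limma 3.58.1 voom values with camera (preset correlation 0.01, adjusted over the lists of a comparison), and again with an estimated correlation and with fry. The lists were 15 gene lists and 16 lists of cell class markers. List counts are given over all genes tested and adjusted over the list alone. Shares of nuclei were compared with two-sided exact permutation tests. Other software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

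Genes to be named were set by rule. In CA1-like nuclei the rule took Fos, Fosb and Junb, the 8 highest and 8 lowest fold changes among genes past the threshold with non-overlapping CPM ranges and a mean of at least 5 CPM in either group, and up to 4 members of each gene list by smallest p. In other classes it took the 3 highest and 3 lowest and the member with the smallest p from 5 lists. Sex-linked genes and unnamed gene models were left out of it. Of the genes it took, 4 are not reported here, and counts of named genes and of results are without them. The rule, the lists, the markers, the tests and most alternatives were fixed before the data were examined. The interaction in classes other than CA1-like, the list tests in interneuron-like nuclei and 5 of the alternatives were added after the data had been seen.

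The side with virus and the side without it came from the same brains, so same-numbered libraries were taken as pairs. In CA1-like sums, the deviations of same-numbered libraries of the Cre cohort from their group means correlated at 0.503 to 0.739 over 7520 genes, and those of differently numbered libraries at -0.650 to 0.382. In interneuron-like sums the values were 0.244 to 0.608 and -0.462 to 0.154 over 9268 genes. The 1 correlation of the deltaCre cohort was 0.535 in CA1-like and 0.314 in interneuron-like sums. Both libraries of pair 2 of the Cre cohort also nearly lacked the Y-linked gene Ddx3y (0.316 and 1.46 CPM), which the other 8 libraries had at 39.2 to 103 CPM. Xist, which is expressed in females, was at 356 to 2123 CPM in all 10 libraries, so those 8 may each hold nuclei of mice of both sexes, and a replicate need not be a single mouse. A fit with the replicate number as a block was therefore run beside the fit without it. The chance shares given for non-overlapping ranges take all libraries as exchangeable and ignore the pairs. They can be too high where paired libraries deviate together.

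Library totals ran from 9191300 to 44597992 UMIs. No replicates were alike within sampling noise, since the chi-square per degree of freedom between libraries of a group was 25.2 to 241 over genes with at least 20 UMIs in the pair. The tests were run on simulated sums with 200 changed genes, drawn from the means and sizes of the real sums. The changed genes were taken among those at 10 CPM or more, so recovery of lower genes is not described. In the simulation of the Cre comparison of CA1-like sums (13885 genes), 6% of genes changed by 1 on the log2 scale were recovered, 37.3% of those changed by 2 and 86.4% of those changed by 3. For the deltaCre comparison (13903 genes) the shares were 1.5%, 4.5% and 56.1%. In interneuron-like sums they were 34.3%, 88.1% and 100% for Cre (11419 genes) and 4.5%, 71.6% and 90.9% for deltaCre (11256 genes). False calls in CA1-like sums were 7 of 93 calls for Cre and 4 of 45 for deltaCre. In interneuron-like sums they were 15 of 163 and 8 of 119. Intervals of shares and limits for a count of 0 (3 counts of the total) cover counting error only.

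Alternatives were DESeq2, limma-voom, relative log expression factors, library totals without composition factors, no filter or a stricter filter on low counts (10 CPM in 2 libraries), the replicate number as a block, a fit of only the 2 groups compared, nucleus minimums of 300 and 1000 genes, doublets kept, sums thinned to the smallest library of the class, injected nuclei with a WPRE UMI only, resolutions 0.5 and 2, and each library left out in turn. Added after the data had been seen were Scrublet's automatic threshold, CA1-like nuclei without 2 sub-clusters that came from a cluster with markers of more than 1 class, the Cre cohort without contralateral libraries 1 and 2, the Cre cohort without pair 3, and shares at a minimum of 300 genes. Where a setting leaves 1 library in an arm, as without contralateral libraries 1 and 2 or without either library of an arm of 2, the spread comes from the other groups of the fit.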

Results

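Single-nucleus RNA sequencing was performed on area CA1 of the mouse hippocampus 4 h after kainic acid, in mice whose Fos, Fosb and Junb genes can be removed by Cre recombinase. These genes code for members of AP-1, a transcription factor that neurons build when they fire. The series concerns a Fos-dependent programme of inhibitory plasticity around the cell bodies of CA1 pyramidal neurons, so the comparisons ask which genes differ in CA1 neurons when AP-1 members are removed from an active hippocampus. The 10 libraries comprised the Cre-injected side (n = 3), its contralateral side without virus (n = 3), the deltaCre-injected side (n = 2) and its contralateral side (n = 2). Each library held between 9191300 and 44597992 UMIs. The lowest total was that of Cre-injected library 2 and the highest that of its cohort's contralateral library 1. After filtering, 76047 nuclei remained, with a median of 896 to 4551 UMIs per nucleus and 4690 to 13734 nuclei per library.

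CA1-like nuclei, named from markers such as Fibcd1, Wfs1 and Mpped1, made up 60.9% ± 21.9 (SD, n = 3) of nuclei on the Cre contralateral side and 11.8% ± 6.04 (n = 3) on the Cre-injected side. Microglia-like nuclei, the resident immune cells of the brain, made up 0.340% ± 0.288 and 33.7% ± 2.90, oligodendrocyte-like nuclei 4.30% ± 4.63 and 14.1% ± 4.19, and nuclei like oligodendrocyte precursors 3.39% ± 2.72 and 12.05% ± 1.39. Astrocyte-like nuclei made up 0.305% ± 0.464 and 7.81% ± 2.47, and CA2-like nuclei 2.99% ± 3.13 and 0.148% ± 0.172. In each of these 6 classes the ranges of both sides did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow; 0.2 after Benjamini-Hochberg adjustment over 12 classes). Interneuron-like nuclei made up 7.21% ± 1.30 and 6.16% ± 2.78 (exact p = 0.6), CA3-like nuclei 1.88% ± 3.02 and 1.72% ± 2.63 (exact p = 0.9) and endothelial-like nuclei 0.877% ± 0.381 and 1.40% ± 0.692 (exact p = 0.4). Of 8 clusters that stayed unnamed and held glial markers, 6 lay mostly on the contralateral and 2 mostly on the injected side of the Cre cohort. A cluster led by Ccl4, Tnf and Ccl3 with 9 microglial markers was 5.55% of contralateral library 1, another with 8 astrocyte markers was 13.3% of it. Both stayed unnamed for few UMIs relative to their libraries and no own marker among the leading genes. The median of the first was 1032 UMIs, against 769 in the largest named microglial cluster. A cluster with markers of CA1 neurons and microglia held 666 nuclei of the Cre-injected libraries and 0 of the contralateral ones. Its mean marker level relative to the highest cluster was 0.299 for CA1 neurons and 0.138 for microglia. Other clusters among the 8 also scored highest for CA1 neurons. Glial shares that count such clusters may therefore include neurons. Counted with all 8, microglia made up 2.74% ± 2.90 and 37.7% ± 3.56, oligodendrocytes 5.43% ± 3.60 and 14.6% ± 4.39 and their precursors 3.73% ± 2.25 and 12.1% ± 1.43, without overlap, while astrocytes made up 6.86% ± 6.41 and 8.20% ± 2.41 and overlapped (exact p = 0.8). With only the 6 added, microglia made up 2.74% and 34.1% ± 2.74 and oligodendrocytes 5.40% and 14.2% ± 4.17, again without overlap.

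In the deltaCre cohort the injected side held 40.8% ± 5.89 CA1-like nuclei (n = 2) against 52.9% ± 4.70 (n = 2) on the other side, and 38.6% ± 2.56 CA3-like nuclei against 10.3% ± 5.62 (exact p = 0.333 for each, the smallest that 2 against 2 allow). Its microglia-like share was 0.0367% ± 0.0317 against 0.0191% ± 0.0271, and 0.407% ± 0.0112 against 0.186% ± 0.143 with the unnamed clusters. Dissection and capture may also set these shares. The sub-clusters of the CA1-like class differed between groups. Of Cre-injected CA1-like nuclei, 54.4% lay in a sub-cluster led by Car12 and Ppp1r1b and 32.3% in one led by Mbd4, Rrad and Thbs1. The first of these was 59.6% from Cre-injected library 2 and the second 93.6% from Cre-injected library 3. Of the Cre contralateral CA1-like nuclei, 46.3% lay in a cluster led by Fbxo10 and Ramp1, which was 95.0% from contralateral library 2, and 22.7% in one led by Ddit4l and Gne. DeltaCre-injected CA1-like nuclei lay at 85.1% in a cluster led by Thbs1, Penk and Nptx2. Values within the class below compare these mixtures.

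**Figure D1:**
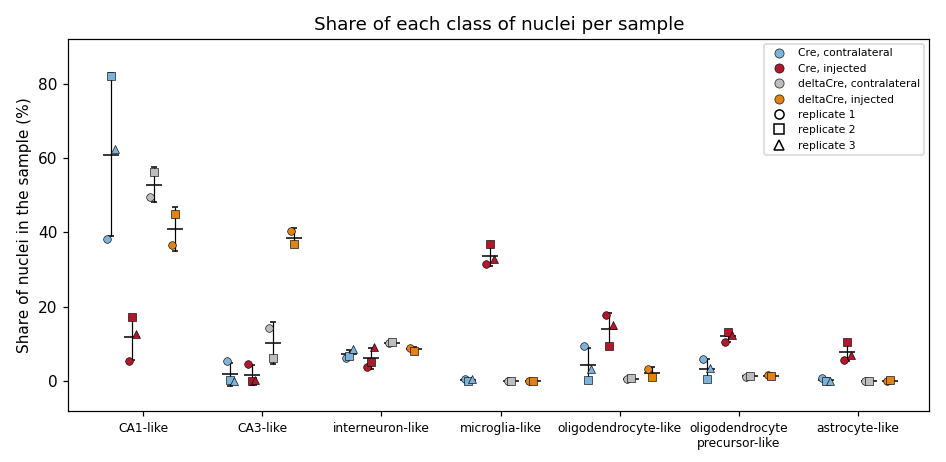
Share of nuclei per class (percent, vertical axis) in each library (points) of the 4 groups, with the group mean and SD as bars. Microglia-like nuclei are at 31.4% or more in the 3 Cre-injected libraries and at 0.525% or less in their contralateral controls.

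Transduction was followed by WPRE, an element of the viral construct. Over all nuclei it reached 926, 1404 and 4163 CPM in Cre-injected libraries 1 to 3 and 10167 and 5437 CPM in the deltaCre-injected libraries, against 0.0249 to 7.85 CPM in the contralateral libraries. In CA1-like sums the mean was 1917 ± 2486 CPM (n = 3) with Cre and 3525 ± 714 CPM (n = 2) with deltaCre, and in interneuron-like sums 4293 ± 4272 and 9349 ± 1710 CPM. The CA1-like values of Cre-injected libraries 1 to 3 were 512, 452 and 4787 CPM, so library 3 carried the mean. In libraries 1 and 2 they lay below the level over all nuclei. With deltaCre the CA3-like sums held more, at 16466 and 6762 CPM. Microglia-like sums of the Cre-injected libraries held 1212 ± 869 CPM (539, 903 and 2192 CPM in libraries 1 to 3). The share of WPRE that came as free RNA from other cells was not estimated. The level in a class therefore need not show that its nuclei were transduced.

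The targeted genes were read in every library first. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand, mm10) stood in CA1-like sums at 34.2, 23.0 and 794 CPM in the Cre contralateral libraries 1 to 3 and at 1.497, 3.24 and 69.3 CPM in the Cre-injected libraries, lower on the injected side in each of the 3 pairs. In the deltaCre cohort it stood at 339 and 804 CPM without virus and 238 and 863 CPM with it. The log2 fold change of Fos was -3.50 with Cre (SE 1.60, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.199; -3.43 and 4.3e-05 with the replicate number as a block) and -0.05 with deltaCre. Fosb (ENSMUSG00000003545, chromosome 7, 19302696 to 19310051, minus strand) stood at 31.2, 30.5 and 576 CPM on the contralateral side and 19.5, 15.4 and 273 CPM on the Cre-injected side (log2 -1.04, and -0.93 past the threshold with the replicate number as a block). Junb (ENSMUSG00000052837, chromosome 8, 84974484 to 84978718, minus strand) stood at 70.5, 54.8 and 2410 CPM and at 59.9, 69.9 and 1643 CPM, a log2 fold change of -0.52 that was 0.24 with library totals alone. All 3 genes were an order of magnitude lower in pairs 1 and 2 than in pair 3, on both sides. Without contralateral library 3, Fos stood at -0.17, Fosb at 1.75 and Junb at 3.25 on the log2 scale, and over all libraries left out in turn Fos ran from -6.80 to -0.17. Each such omission broke a pair. The first kept Cre-injected library 3 and set it against contralateral libraries 1 and 2, where all 3 genes were low. It therefore does not show a smaller effect within pairs. Fos and Junb without the whole of pair 3 are given with the processing settings.

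In interneuron-like sums Fos stood at 448, 250 and 925 CPM on the contralateral side and 12.1, 4.06 and 59.4 CPM on the Cre-injected side, and fell by 4.27 on the log2 scale (SE 0.84, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0287). In the deltaCre cohort it was 755 and 996 CPM without virus and 798 and 893 CPM with it. Fosb had a log2 fold change of -1.66 with Cre and Junb of -0.38, and neither passed the threshold, while both did with the replicate number as a block (-1.97 and -0.87, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 2.2e-06 and 0.0261). Tags of this assay lie near the 3' end of a transcript, and the deleted exons are not given in the sources used here. A tag outside them would not show a deletion, so the levels of Fosb and Junb do not check the labels.

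**Figure D2:**
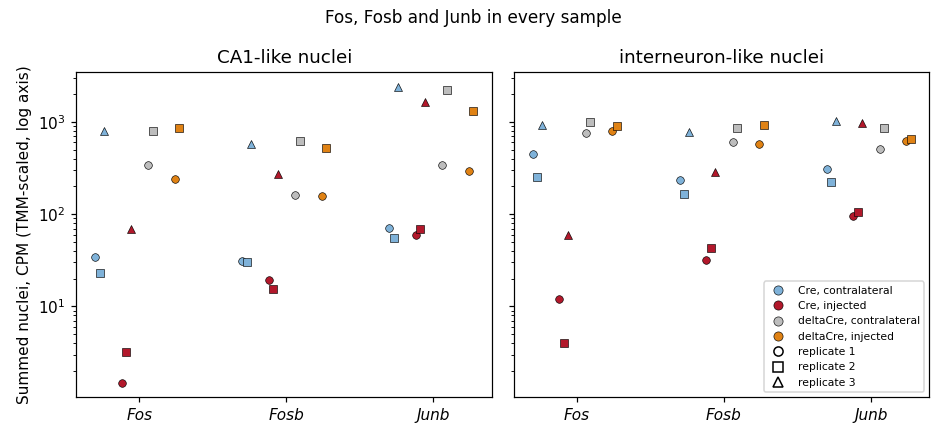
Levels of Fos, Fosb and Junb (CPM, log axis) in CA1-like and interneuron-like sums of each library, with colours for the 4 groups and marker shapes for the replicate number. Fos lies lower on the Cre-injected side in all 3 pairs of both classes, from 794 to 69.3 CPM in CA1-like sums of pair 3.

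CA1-like nuclei of the Cre-injected side carried more transcripts of interferon and immune genes than those of the side without virus. Ifi27l2a, an interferon-induced gene, rose from 0.0209 ± 0.0362 to 12.2 ± 3.78 CPM (n = 3 and 3), with 1 UMI over the contralateral libraries and 102 over the injected ones (ratio of pooled levels 984, 95% exact interval of counting error 173 to 39255). The antigen-presentation genes H2-K1 and B2m rose from 1.90 ± 0.968 to 38.8 ± 13.6 CPM (log2 4.35) and from 2.76 to 26.8 CPM (3.28). Bst2 and Oasl2, antiviral effectors, rose by 5.02 and 4.24 on the log2 scale. Trem2, Lyz2, Cst7 and Axl, genes of phagocytes, rose by 4.50, 4.92, 3.19 and 3.47, to levels of 5.53 to 9.78 CPM. Of the interferon list 12 of 16 measured members rose (15 adjusted over the list alone; median 3.29; camera, Benjamini-Hochberg adjusted p = 6.1e-13, and adjusted p = 0.065 with an estimated correlation). Of the activated microglia list 6 of 10 rose and Lpl, lipoprotein lipase, fell (8 and 1 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 3.6e-05, and adjusted p = 0.18 with an estimated correlation). Markers of microglia moved with them in these sums: 6 of 9 rose (8 adjusted over the list alone; median 1.95; camera, Benjamini-Hochberg adjusted p = 9.1e-07, and adjusted p = 0.096 with an estimated correlation), in libraries of which 33.7% of nuclei were microglia-like.

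Inhba (ENSMUSG00000041324, chromosome 13, 16011851 to 16031621), which codes for a subunit of activin and is induced by activity, fell from 768 ± 572 to 24.1 ± 3.28 CPM (log2 -4.99, SE 0.88), against 1247 and 1158 CPM in the deltaCre cohort. Ptgs2, the inducible prostaglandin synthase cyclooxygenase-2, fell by 3.66 on the log2 scale (-4.63 to -1.90 with libraries left out in turn, past the threshold in 2 of 6 cases, and -0.98 without the sub-clusters named above), and Npy2r, a receptor for neuropeptide Y, by 4.31. The potassium channel genes Kcnj3 and Kcnh7 fell by 3.02 and 2.93. The GABA-A receptor genes Gabra2 and Gabrb1 fell by 2.56 and 2.45, for example Gabra2 from 1384 ± 749 to 235 ± 45.0 CPM. Gria2, a subunit of AMPA receptors, fell by 2.32, and the synaptic adhesion gene Nlgn1 by 1.74. The level of Gabra2 in the deltaCre-injected libraries was 1169 CPM. Ndst3 and Bmpr1b, also among the genes with the lowest fold changes, lead clusters that make up the class and are not read as changes here.

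In the inhibitory synapse list 7 of 20 members fell and Iqsec3, an exchange factor of inhibitory synapses, rose (11 and 1 adjusted over the list alone; median -1.17; camera, Benjamini-Hochberg adjusted p = 1.2e-06, and adjusted p = 0.18 with an estimated correlation). In the excitatory synapse list 7 of 22 fell (9 fell and 1 rose adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 8.1e-05, and adjusted p = 0.065 with an estimated correlation). Its median of -0.53 was 0.13 with library totals alone, a scaling that moved the median of all genes from 0.03 to 0.69, and the list of inhibitory synapse genes kept its sign (-0.47). The reactive astrocyte list passed with 3 of 11 higher, among them Gfap, a filament protein of astrocytes, at 1.93 (5 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.00533, and adjusted p = 0.18 with an estimated correlation). Markers of blood immune cells (0.0192, and 0.27 with an estimated correlation), of CA1 pyramidal neurons (0.0431, lower, and 0.49) and of astrocytes (0.0431, higher, and 0.55) passed by Benjamini-Hochberg adjusted p of camera.

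Of 24 late-response genes Inhba and Ptgs2 fell and Blnk, an adaptor protein of immune receptors, rose by 2.39 (2 higher and 4 lower adjusted over the list alone). The list did not pass (camera, Benjamini-Hochberg adjusted p = 0.126, and 0.0119 with the replicate number as a block). Bdnf, Scg2 and Nptx2, which code for a neurotrophin, a neuropeptide precursor and a synaptic pentraxin, stood at -1.43, -2.75 and -0.24 and did not pass, while Bdnf and Scg2 passed with the replicate number as a block (-1.59 and -2.67, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00287 and 4.6e-05). With libraries left out in turn Bdnf ran from -3.20 to -0.27 and Scg2 from -3.99 to -1.41, and Nptx2 was at 0.46 with library totals alone. None of 18 immediate-early genes passed, with a median of -0.11 (0.64 with library totals alone), a mean of 0.10 and a test in the lower direction (camera, Benjamini-Hochberg adjusted p = 0.353). The 11 genes of MAP kinase feedback had no member past the threshold (adjusted p = 0.0926 by camera with Benjamini-Hochberg, 0.0264 with the replicate number as a block), and the list of the 3 deleted genes was at 0.353 (0.0264 with the block). Pam and Cpe, enzymes that process neuropeptides, and Cadps2, a secretion factor, fell by 2.00, 1.46 and 1.60, 3 of 15 members of the dense-core vesicle list (4 adjusted over the list alone; adjusted p = 0.126 by camera with Benjamini-Hochberg). Of 23 potassium and HCN channel genes 5 fell and Kcnc1 and Kcnh5 rose (6 and 4 adjusted over the list alone; adjusted p = 0.126 by camera with Benjamini-Hochberg; median -0.01, or 0.67 with library totals alone, and mean -0.46). Among the other AP-1 genes Fosl1 rose by 1.94, 1 of 13 measured (2 adjusted over the list alone). Cdkn1a, a cell cycle inhibitor, was 1 of 15 p53 genes past the threshold (2.29) and Ddit3, a stress-induced factor, 1 of 15 protein folding genes (2.03), and their values were -0.11 and -0.22 without the sub-clusters named above. Mitochondrial transcripts had no member of 11 past the threshold.

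Across all 15285 genes tested, 751 were higher and 448 lower on the Cre-injected side (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and the ranges of both sides did not overlap in 27.3% of the genes, where chance gives 10%. The adjusted p-values of the 38 named genes past the threshold ran from 0.000543 for Ifi27l2a to 0.0457 for BC030500, and 22 of them stayed past it whichever library was left out. The share of higher calls was 62.6%, against 46.9% of 1881 calls by DESeq2, 50% with relative log expression factors and 93.8% of 3454 calls with library totals alone. With the replicate number as a block 3346 genes passed. Counts were 252 without contralateral library 1, 375, 468 and 664 without Cre-injected libraries 1, 2 and 3, 415 with only the 2 groups in the fit, 417 with sums thinned to the smallest library and 555 with nuclei of at least 1000 genes. Without the sub-clusters led by Car12 and by Mbd4, which held most of the Cre-injected CA1-like nuclei, 294 such nuclei remained (21 to 164 per library) and 2 genes passed. Of 34 named genes with a value there, 32 kept their direction. The median of those that had been higher went from 3.28 to 2.61 and of those that had been lower from -2.93 to -0.99, with H2-K1 at 3.86, Inhba at -3.16, Gabra2 at -1.44, Gria2 at -0.90 and Kcnh7 at -0.86.

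**Figure D3:**
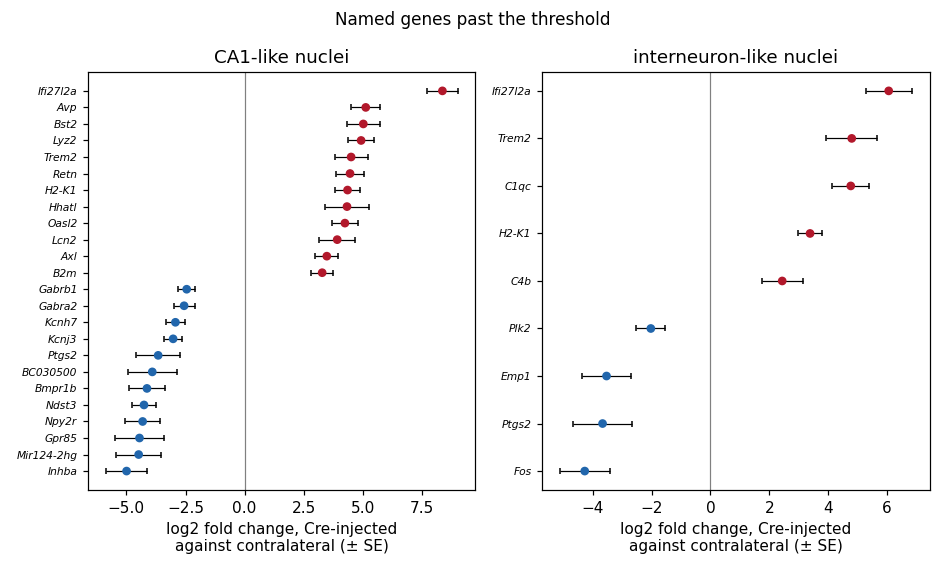
Log2 fold changes (points, horizontal axis, bars for the SE) of named genes past the threshold between the Cre-injected and contralateral sides, in CA1-like sums (the highest 12 and lowest 12) and interneuron-like sums. In CA1-like sums Inhba lies at -4.99 and H2-K1 at 4.35, and in interneuron-like sums H2-K1 lies at 3.38 and Plk2 at -2.02.

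**Figure D4:**
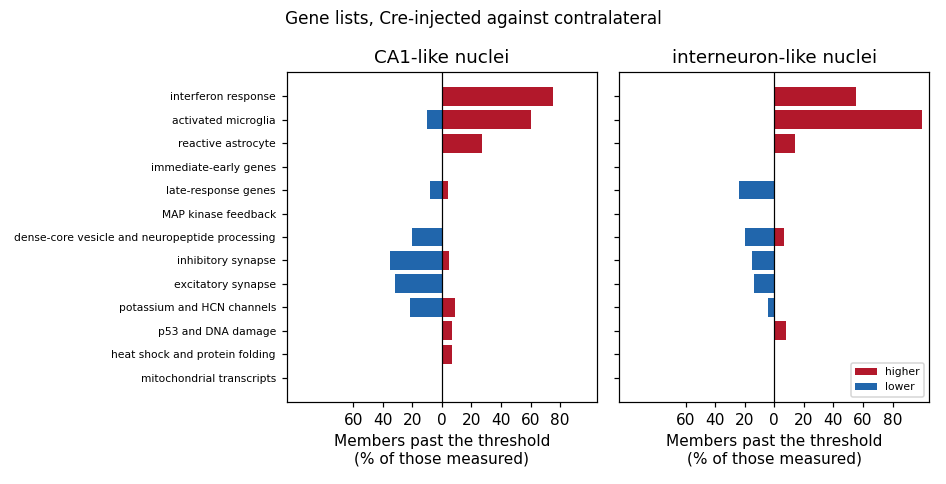
Share of the measured members of each gene list that passed the threshold (percent, right for higher and left for lower) on the Cre-injected against the contralateral side, in CA1-like and interneuron-like sums. In the interferon list 12 of 16 members were higher in CA1-like sums and 5 of 9 in interneuron-like sums.

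DeltaCre served as the control for injection and virus. On that side H2-K1 stood at 25.9 ± 15.6 CPM in CA1-like sums against 1.01 CPM on the other side, B2m at 10.0 against 2.07 CPM, and Blnk at 19.2 against 2.54 CPM (n = 2 and 2). Inhba stood at 1158 ± 1119 against 1247 CPM. No gene passed (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), 769 had an unadjusted p under 0.05, DESeq2 called 47, limma-voom 0 and the fit with the replicate number as a block 163. The ranges did not overlap in 38.1% of genes, where chance gives 33.3% if pairs are ignored, a share that can be too high for paired libraries. Of 8 lists past the threshold of camera, the oligodendrocyte markers had a median of 2.78 (Benjamini-Hochberg adjusted p = 1.8e-11, and adjusted p = 0.425 with an estimated correlation; 6 higher adjusted over the list alone). The interferon list had a median of 0.82 (0.000107 and 0.425; 3 higher adjusted over the list alone) and the inhibitory synapse list of -0.54 (0.000978 and 0.436). The activated microglia list (0.0413) and the p53 list (0.0334) passed without the block and not with it (0.11 and 0.0704), and with an estimated correlation 0 of the 29 lists passed.

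The interaction asked whether the difference between sides depended on active Cre. In CA1-like sums Fos had the values given above, with an interaction of -3.44 on the log2 scale (SE 2.35, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.658), which passed with the replicate number as a block (-3.23, 0.0093) and ran from -6.77 to -0.12 with libraries left out in turn. No gene passed (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), 1552 had an unadjusted p under 0.05, DESeq2 called 141, limma-voom 0 and the block 157, and 17 passed without contralateral libraries 1 and 2 of the Cre cohort, where that arm holds library 3 alone and the other groups supply the spread. The interferon list was higher with Cre beyond deltaCre (median 1.70; camera, Benjamini-Hochberg adjusted p = 0.000125, and adjusted p = 0.369 with an estimated correlation). The late-response, excitatory and inhibitory synapse lists were lower, with medians of -0.82, -0.32 and -0.56 (0.00436, 0.0019 and 0.0053, and adjusted p = 0.533, 0.185 and 0.386 with an estimated correlation), and with library totals alone the medians were -0.11, 0.28 and 0.11 where that of all genes was 0.65. In all 10 lists passed with the preset correlation, and 0 with an estimated one. With the replicate number as a block the deleted genes (0.0493), the immediate-early (0.0339), MAP kinase feedback (0.00702) and dense-core vesicle lists (0.0105) passed as well, all lower, by Benjamini-Hochberg adjusted p of camera.

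Between the injected sides of the cohorts, Kcnh4 and Kcnc4, potassium channel genes, were higher with Cre than with deltaCre (10.7 ± 2.65 against 0.720 CPM, log2 3.88, and 76 against 2 UMIs, a ratio of pooled levels of 52.96 with an exact 95% interval of 14.2 to 445). So was Grm4, a metabotropic glutamate receptor, at 30.6 ± 13.2 against 1.87 CPM (log2 4.00). Inhba was lower by 5.58 on the log2 scale, Sema3e, an axon guidance signal, by 3.99 (182.5 ± 31.3 against 2898 ± 902 CPM), Bace2, a protease, by 4.68, and Dpysl3, a protein of growth cones, by 3.89. Gabra2, Gria2 and Kcnh7 were lower by 2.32, 1.91 and 2.18. Their adjusted p-values lay between 0.0266 and 0.0446 (edgeR quasi-likelihood, Benjamini-Hochberg). Without the sub-clusters led by Car12 and by Mbd4, Gabra2, Gria2 and Kcnh7 stood at -1.25, -0.53 and -0.16. All 19 named genes with a value there kept their direction. The median of the 12 lower ones went from -3.67 to -1.84 and of the 7 higher ones from 4.34 to 3.38. The immediate-early and late-response lists were lower in the Cre cohort, with medians of -0.81 and -1.25 (-0.11 and -0.57 with library totals alone, all genes 0.96; camera, Benjamini-Hochberg adjusted p = 7.1e-05 and 1.5e-05, and adjusted p = 0.5 and 0.461 with an estimated correlation), and 13 lists passed in all, 0 with an estimated correlation and 3 by fry. The immediate-early list also had a median of -0.72 between the contralateral sides (camera, Benjamini-Hochberg adjusted p = 0.0186, and adjusted p = 0.926 with an estimated correlation) and of -0.08 in the interaction, where it passed as lower only with the block (0.0339). The late-response list had medians of -0.46 and -0.82 in these comparisons.

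In that comparison 36 genes were higher and 109 lower (24.8% higher, against 89.7% of 786 calls with library totals alone, a scaling under which the median of all genes was 0.96). The ranges did not overlap in 39.6% of genes, where chance gives 20%. DESeq2 called 954 genes and limma-voom 100. The count was 0 without Cre-injected library 1 or 2, 0 without either deltaCre-injected library, 296 without Cre-injected library 3, 614 with only these groups in the fit, 225 with no filter, 241 and 445 at resolutions 0.5 and 2, 0 with nuclei of at least 1000 genes, 1 without the sub-clusters, 850 without contralateral libraries 1 and 2 (which are in the fit and not in the comparison) and 2590 without pair 3. None of the 21 named genes past the threshold kept its call under every one of these omissions.

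Contralateral sides were compared between the cohorts. Fos, Fosb and Junb had log2 differences of -1.01, -0.88 and -0.59 in CA1-like sums of the Cre cohort against the deltaCre cohort. No gene passed (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), 1832 had an unadjusted p under 0.05, DESeq2 called 17 and limma-voom 0. The count was 5 without contralateral library 3 of the Cre cohort and 2327 without pair 3. The immediate-early list had a median of -0.72 (camera, Benjamini-Hochberg adjusted p = 0.0186, and adjusted p = 0.926 with an estimated correlation). Non-overlapping ranges made up 30.02% of genes, where chance gives 20%.

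Interneuron-like nuclei were named from Gad1, Gad2 and other markers of inhibitory neurons. On the Cre-injected side Bdnf and Nptx2 fell, beside Fos, by 2.31 and 1.46 on the log2 scale, Nrn1, which codes for a synaptic growth factor, by 2.16, Plk2, an activity-induced kinase, from 157 ± 95.5 to 36.7 ± 24.7 CPM (log2 -2.02). Of 21 late-response genes 5 fell (10 adjusted over the list alone; median -1.46; camera, Benjamini-Hochberg adjusted p = 0.000475, and adjusted p = 0.408 with an estimated correlation), and of 17 immediate-early and 11 MAP kinase feedback genes none passed (immediate-early median -0.73; camera, Benjamini-Hochberg adjusted p = 0.00176, and adjusted p = 0.578 with an estimated correlation). Gad2, which makes GABA, fell by 1.17, the receptor gene Erbb4 by 0.99 and Lamp5, a marker of an interneuron subclass, by 2.08, among 5 of 13 interneuron markers that fell (8 adjusted over the list alone; median -1.12; camera, Benjamini-Hochberg adjusted p = 1.2e-05, and adjusted p = 0.271 with an estimated correlation). Gabra2 fell by 1.34, and Pcsk2, a prohormone convertase, rose by 1.09. Of 4 CA1 pyramidal markers measured in these sums Mpped1 fell (median -0.53). Whether free RNA from CA1 neurons added to the lower genes was not tested in interneuron-like sums. Apart from Fos and Plk2, the genes named here were picked from the lists after their values had been seen.

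Interferon and phagocyte genes were higher in the same sums. Ifi27l2a rose from 0.121 ± 0.209 to 16.1 ± 1.81 CPM (1 and 57 UMIs, ratio of pooled levels 126, 95% exact interval 21.7 to 5047), H2-K1 from 5.18 ± 1.29 to 53.3 ± 23.2 CPM (log2 3.38), and C1qc, a complement gene of microglia, from 1.59 to 43.6 CPM (4.76). Of 9 measured interferon genes 5 rose (8 adjusted over the list alone; median 2.71; camera, Benjamini-Hochberg adjusted p = 2.2e-07, and adjusted p = 0.045 with an estimated correlation). Microglial markers rose in 4 of 8 cases (camera, Benjamini-Hochberg adjusted p = 0.000192, and adjusted p = 0.271 with an estimated correlation). These list tests were added after the data had been seen, and of 14 lists past the threshold only the interferon list passed with an estimated correlation.

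Of 12086 genes tested in interneuron-like sums, 526 were higher and 392 lower (edgeR quasi-likelihood with Benjamini-Hochberg adjustment; 57.3% higher, and 85.0% of 1577 calls with library totals alone). The ranges did not overlap in 27.2% of genes, where chance gives 10%. The count was 115, 1342 and 253 without contralateral libraries 1 to 3, and 114 and 1512 without Cre-injected libraries 2 and 3. It was 3152 with the replicate number as a block, 527 with only the 2 groups in the fit, 538 with thinned sums, 2032 with no filter and 506 with contralateral library 3 as the only library of its arm. Of the 9 genes named by the rule 3 kept their call whichever library was left out. With deltaCre no gene passed (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), 472 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom 0, the block 31, the fit of 2 groups 9 and the fit with no filter 28. There H2-K1 stood at 30.6 ± 1.38 CPM against 5.39 CPM.

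In the interaction of interneuron-like sums, added after the data had been seen, Adgrv1, an adhesion receptor, Mylip, a ubiquitin ligase, and Znhit1, a chromatin remodelling subunit, were higher with Cre beyond deltaCre by 2.69, 2.58 and 2.55 on the log2 scale. Mylip went from 200.5 to 848 CPM between the sides with Cre and from 585 to 412 CPM with deltaCre. The fourth call was the gene model Gm17660 (2.53), named only after its values were seen. Each had an adjusted p of 0.0371 (edgeR quasi-likelihood, Benjamini-Hochberg). The interaction of Fos was -4.22 (adjusted p = 0.237 by edgeR with Benjamini-Hochberg, and -4.50 with 2.4e-07 with the replicate number as a block). The count of 4 was 0 without any 1 of contralateral libraries 1 to 3, Cre-injected library 2 or the deltaCre libraries, 2 without Cre-injected library 1 and 191 without Cre-injected library 3. It was 45 by DESeq2, 0 by limma-voom, 22 with library totals alone, 346 with no filter, 978 with the block and 171 without pair 3.

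Microglia-like nuclei of the Cre-injected side (n = 3, against the 2 contralateral libraries with enough nuclei) held Lgals3bp, Ddx60 and Ifi204, genes induced by interferon, at 277, 242 and 224 CPM, with no UMI in the controls, whose sums held 81341 UMIs. Contralateral library 1 entered these sums with 40 nuclei. A further 423 of its nuclei lay in the unnamed cluster with microglial markers led by Ccl4 and were left out. Apoe, a lipid carrier of activated microglia, rose from 40.6 to 1266 CPM (log2 4.91) and H2-K1 from 46.6 to 1195 CPM (4.81). Inhba fell by 5.44, Mal2 by 4.93 and Plk2 by 3.66. In oligodendrocyte-like sums H2-D1, a class I antigen gene, rose from 2.14 to 355 CPM (6.64), and C4b, complement component 4, from 6.07 to 408 CPM (5.79), and Inhba and Bdnf fell by 5.01 and 3.19. In precursor-like sums Oasl2 rose from 5.97 to 114 CPM (2 and 277 UMIs, ratio of pooled levels 69.3, 95% exact interval 19.0 to 575), C4b by 5.58 and H2-D1 by 3.83, and Scg2, Ptgs2 and Inhba fell by 4.72, 4.33 and 3.68. In endothelial-like sums Irf7, the interferon regulatory factor, rose from 53.1 ± 25.5 to 386 ± 142 CPM (3.01), and Serpina3n, a protease inhibitor, by 2.92, and Homer1, a synaptic scaffold, fell by 3.22. Scgb3a1, a secretoglobin, rose from 3.29 to 294 CPM (2 and 157 UMIs, ratio of pooled levels 83.8, 95% exact interval 22.8 to 698). In the 4 subicular or cortical-like calls Sema5a and Myo7b were higher by 3.18 and 2.50 and Etv1 and Nrsn1 lower by 4.05 and 3.44.

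Counts in these classes (higher and lower, edgeR quasi-likelihood with Benjamini-Hochberg adjustment) were 219 and 72 in microglia-like sums, 194 and 97 in oligodendrocyte-like, 168 and 86 in precursor-like, 224 and 116 in endothelial-like and 2 and 2 in subicular or cortical-like sums. Of microglia-like calls 75.3% were higher, against 40.4% by DESeq2, 63.0% with relative log expression factors and 42.3% of 163 calls with library totals alone. Of oligodendrocyte-like calls 66.7% were higher, against 77.4% with library totals alone. These counts changed when single libraries were left out. Each omission also leaves fewer libraries to test, so how much any library carried was not tested. The microglia-like count of 291 was 84 and 0 without contralateral libraries 1 and 3, 61 without Cre-injected library 1 and 452 without Cre-injected library 3. The oligodendrocyte-like count of 291 was 188 without contralateral library 3 and 136 and 86 without Cre-injected libraries 1 and 2. The precursor-like count of 254 was 71, 458 and 57 without contralateral libraries 1 to 3 and 54, 22 and 65 without Cre-injected libraries 1 to 3. The endothelial-like count of 340 was 136 without contralateral library 3 and 157 without Cre-injected library 2. The subicular count of 4 was 0 and 2 without contralateral libraries 1 and 3 and 13 and 68 without Cre-injected libraries 1 and 3. With the replicate number as a block the counts were 547 in oligodendrocyte-like, 538 in precursor-like, 736 in endothelial-like and 23 in subicular sums.

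With deltaCre no gene passed in oligodendrocyte-like, precursor-like or CA2-like sums (edgeR quasi-likelihood with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 475, 668 and 232 genes, and DESeq2 called 0 in the first of these and 3 in the second. With the replicate number as a block 1, 32 and 161 genes passed. Leaving out deltaCre contralateral library 2 gave 1 gene in oligodendrocyte-like sums, and leaving out library 1 of that group 1 gene in precursor-like sums. The interaction in precursor-like sums called 3 genes (added after the data had been seen), of which Rnls, a flavin enzyme, went from 48.6 to 144 CPM with Cre and from 174 to 12.6 CPM with deltaCre (log2 5.07, adjusted p = 0.0254 by edgeR with Benjamini-Hochberg). The others were the gene models Gm3448 (3.14) and Gm17660 (2.90), named after their values were seen. That count was 0 without contralateral library 1, Cre-injected library 1 or 2, deltaCre-injected library 1 or deltaCre contralateral library 2, and 1 without contralateral library 3, Cre-injected library 3 or deltaCre-injected library 2. Without deltaCre contralateral library 1 it was 5. The block gave 11 and DESeq2 5. Precursor-like sums also mix clusters. The cluster led by Bmp4 held 76.8% of deltaCre-injected precursor-like nuclei and 33.3% of those on the other side. With Cre the shares were 43.9% and 26.0%. In oligodendrocyte-like sums the interaction called 0 genes, with 572 at an unadjusted p under 0.05, 3 by DESeq2, 19 with the block, 2 without contralateral library 1 or 2, 3 without Cre-injected library 3, 4 without deltaCre-injected library 1 and 1 without deltaCre contralateral library 2.

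CA3-like nuclei differed between the sides with deltaCre. H2-K1 rose from 1.59 to 125 ± 60.5 CPM (log2 6.17, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 9.3e-11; n = 2 and 2) and Blnk from 3.81 to 61.2 CPM (3.99), and Zfp804a, a zinc finger gene, fell from 5400 to 432 CPM (-3.64) and Slc25a24, a mitochondrial carrier, by 3.75. Here 490 genes were higher and 206 lower, with non-overlapping ranges in 59.9% of genes where chance gives 33.3%. Of deltaCre-injected CA3-like nuclei 81.4% lay in a cluster led by Lrrc10b and Grhl2, and 98.8% of those on the other side in a cluster led by Aldh1a3 and Slit2. Of these calls 70.4% were higher, against 26.8% of 127 calls by DESeq2, 57.8% with relative log expression factors and 85.4% of 989 with library totals alone. The count of 696 was 57 and 4 without deltaCre contralateral libraries 1 and 2, 83 and 368 without deltaCre-injected libraries 1 and 2, 0 with thinned sums and 3389 with the block.

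With Cre, 2 libraries per side had enough CA3-like nuclei (contralateral libraries 1 and 2, Cre-injected libraries 1 and 3). Ifi27l2a, C1qa and C1qc stood at 14.8, 10.1 and 9.85 CPM with no UMI in the controls. Fam46a, a poly(A) polymerase, fell from 114 to 0.861 CPM (282 and 3 UMIs, ratio of pooled levels 35.0, 95% exact interval 11.8 to 171), and Tac1, the precursor of substance P, by 3.38 with overlapping ranges. Of 11884 genes, 168 were higher and 63 lower (edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and of the injected nuclei 71.3% lay in a cluster that was 97.9% from Cre-injected library 1. The count of 231 was 5 and 83 without contralateral libraries 1 and 2, 613 without Cre-injected library 1, 85 by DESeq2 and 0 with thinned sums. The interaction, added after the data had been seen, called 1 gene, the gene model A330050F15Rik (-7.20, adjusted p = 0.000682 by edgeR with Benjamini-Hochberg), named after its values were seen. That count was 48 and 18 without Cre-injected libraries 1 and 3, 0 without contralateral library 1 or either deltaCre contralateral library, 2 without either deltaCre-injected library and 0 by DESeq2.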

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

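Chosen only after the results had been seen were the tests of a loss of CA1-like nuclei, of dissection, of injection and virus, of short-lived RNA, of depth per nucleus and of free RNA from CA1 neurons, the interaction outside CA1-like nuclei and the list tests in interneuron-like nuclei.

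The difference between sides itself differed between the Cre and deltaCre arms for 8 gene results, by the interaction in edgeR with Benjamini-Hochberg adjustment. On the log2 scale the interactions were 2.69 for Adgrv1, 2.58 for Mylip, 2.55 for Znhit1 and 2.53 for Gm17660 in interneuron-like sums, 5.07 for Rnls, 3.14 for Gm3448 and 2.90 for Gm17660 in precursor-like sums, and -7.20 for A330050F15Rik in CA3-like sums. Each of the 3 counts fell to 0 when a single library was left out, such as contralateral library 1.

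The same difference between arms was found for 10 lists in CA1-like sums by camera with a preset correlation and Benjamini-Hochberg adjustment. Higher with Cre beyond deltaCre were the interferon list (adjusted p = 0.00013), the activated microglia list (0.025) and the markers of microglia (0.0026) and of blood immune cells (0.0083). Lower were the excitatory synapse (0.0019) and inhibitory synapse lists (0.0053), late-response genes (0.0044), mitochondrial transcripts (0.0044) and the markers of CA1 pyramidal neurons (0.016) and of oligodendrocytes (0.0013). In interneuron-like sums 13 lists passed. Higher there were the interferon, activated microglia, microglia marker and blood immune marker lists (0.0084 each) and subicular markers (0.02, and 0.0535 with the replicate number as a block). Lower were the interneuron markers (0.0012), immediate-early genes (0.0036), the deleted genes (0.015), MAP kinase feedback (0.017), late-response genes (0.02), mitochondrial transcripts (0.022), and the dense-core vesicle and heat shock lists (0.0084 each). With an estimated correlation 0 of the lists passed in either class.

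Signals outside the gene measurement were also present. WPRE was at 926 to 4163 CPM in the Cre-injected libraries and at 5437 and 10167 CPM in the deltaCre-injected libraries, against at most 7.85 CPM in the contralateral libraries. An unnamed cluster with markers of both CA1 neurons and microglia held 2.68%, 4.44% and 3.67% of the nuclei of the Cre-injected libraries, 0 in the contralateral libraries and 0.0572% and 0 in the deltaCre-injected ones.

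Cre-injected libraries held fewer CA1-like and more microglia-like nuclei than their contralateral controls. A loss of CA1-like nuclei alone is argued against, since the ratio of microglia-like to interneuron-like nuclei was at least 41.4 times higher. The factor was 3.99 with the unnamed clusters that held microglial markers counted (3.59 with only those that lay mostly on the contralateral side). The minimum of genes per nucleus is argued against too, since the difference in the microglia-like share was 36.9 points at a minimum of 300 genes. Interneuron-like nuclei were themselves fewer per precursor-like nucleus with Cre. In libraries 1 to 3 that ratio was 0.375, 0.399 and 0.743, against 1.02, 11.4 and 2.44 on the contralateral side. A loss that includes interneuron-like nuclei would also raise the microglial ratio. Counts beside precursor-like nuclei, chosen after the data had been seen, leave neurons out. Contralateral libraries 1 to 3 held 40, 1 and 67 microglia-like and 459, 76 and 487 precursor-like nuclei. Cre-injected libraries held 1548, 1984 and 2647 against 517, 706 and 1007. With unnamed clusters that lay mostly on the contralateral side, mean shares were 2.74% and 3.73% there and 34.1% and 12.1% with Cre. These values argue against a loss of neurons alone. A loss beside other changes stays open. Dissection and preparation of the injected side stays open: the highest microglia-like share of a deltaCre-injected library was 0.05909%, but the cohorts may have been prepared apart, which keeps both from being told apart. A reaction of the tissue that depends on Cre also stays open as a hypothesis, since the difference of shares between arms was not tested.

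Interferon and microglial genes were higher in CA1-like sums of Cre-injected libraries, and Inhba was lower in microglia-like, oligodendrocyte-like, precursor-like and endothelial-like sums (in the last with 0 against 32 UMIs). Free RNA from other cells goes with the interferon genes: their excess relative to the whole library was 1.241 to 1.62 times that of microglial markers, within the bound of 2 set beforehand. For the microglial markers it stays open, since their excess in CA1-like over interneuron-like sums had ratios of 2.438, 1.39 and 0.805, and so does free RNA from CA1 neurons in the glial and endothelial sums, where CA1 markers had a median of -0.631 in oligodendrocyte-like, -1.16 in precursor-like and -2.11 in microglia-like sums, from few genes, and no such marker was tested in endothelial-like sums. Injection and virus without recombination cannot be told apart from Cre for the interferon list, since its interaction had an adjusted p of 0.3694 with an estimated correlation. The bound of 2 needed only 1 library within it, so meeting it does not exclude a response of CA1 neurons. In interneuron-like sums of libraries 1 to 3 the interferon excess was 0.133, 0.166 and 0.169, against 0.0596, 0.0853 and 0.182 for microglial markers. With deltaCre the list had a median of 0.82 in CA1-like sums, where at most 0.0591% of nuclei were microglia-like. An interferon response of CA1 neurons that depends on Cre may exist beside free RNA and the virus and was not tested apart from them.

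Immediate-early genes were low in CA1-like sums of contralateral libraries 1 and 2 of the Cre cohort, with median log2 differences from library 3 of -3.31 and -3.83. A loss of short-lived RNA in preparation alike in all nuclei is argued against, since the differences in interneuron-like sums were -0.995 and -1.96, a gap between classes of -2.31 and -1.87. Depth per nucleus is argued against too, since library 2 had a median of 1415 UMIs per CA1-like nucleus and library 1 of 6610, on either side of the 2237.5 of library 3. A CA1-like cluster led by Hspa1b, Hspa1a, Egr1, Egr4 and Junb held 1312 nuclei of contralateral library 3 and 0 of libraries 1 and 2. That cluster also held 8 and 410 nuclei of deltaCre contralateral libraries 1 and 2 and 52 of Cre-injected library 3, so it was not particular to contralateral library 3. Fos in CA1-like sums was 339 and 804 CPM in the deltaCre contralateral libraries, against 794 CPM in contralateral library 3 of the Cre cohort. The libraries compared thus hold different mixtures of clusters, and a rise in library 3 was not tested. How the replicates differed in seizure strength or in time after kainic acid is not given in the sources used here, so a difference in activity between them stays open as a hypothesis. Without contralateral libraries 1 and 2, which leaves library 3 alone in its arm, the log2 fold change of Fos between contralateral sides was 0.47 in place of -1.01.

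Of the 10 splits of the 6 libraries of the Cre cohort into groups of 3, 1 gave as many genes as the real split, the real one itself, in each of 5 classes, and 10 splits are too few for a share under 0.05. The real count and the highest of the others were 1199 and 0 in CA1-like, 918 and 191 in interneuron-like, 340 and 1 in endothelial-like, 291 and 2 in oligodendrocyte-like and 254 and 0 in precursor-like sums. Of the 4 splits that part all pairs, those other than the real one gave 0 genes.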

How the results depend on the processing

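Chosen after the data had been seen were the automatic doublet threshold, CA1-like sums without the split sub-clusters, the Cre cohort without contralateral libraries 1 and 2 or without pair 3, and shares at a minimum of 300 genes. Over 220 results, 3500 values under other settings had the same direction and side of the threshold (counts within 1.5 times), 598 were weaker, 30 stronger, 223 moved and 56 reversed. Where a setting reduces libraries, nuclei or tested genes that is its construction, and for the other values given here the cause was not tested. The block ended no call of a named gene, and the calls it added or counts it moved are given beside them or here. In interneuron-like sums it added, by camera, the reactive astrocyte (0.0312) and mitochondrial lists (0.00707) with Cre and the late-response (0.00161) and heat shock lists (0.0463) with deltaCre, and it changed no other list call. Without contralateral libraries 1 and 2, or without 1 library of an arm of 2, the arm holds 1 library and the other groups supply the spread.

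Counts for Cre-injected against contralateral sums were as follows. CA1-like (1199): DESeq2 1881, library totals 3454, block 3346, 2 groups 415, thinned 417, at least 1000 genes 555, without the split sub-clusters 2, libraries left out 252 to 1370. Interneuron-like (918): totals 1577, no filter 2032, block 3152, 2 groups 527, thinned 538, without contralateral libraries 1 and 2 506, left out 114 to 1512. CA3-like (231): DESeq2 85, no filter 144, stricter filter 114, limma-voom 97, 2 groups 30, thinned 0, left out 5 to 613. Endothelial-like (340): stricter filter 559, block 736, thinned 204, doublets kept 577, automatic threshold 511, left out 136 to 454. Microglia-like (291): totals 163, no filter 548, limma-voom 579, thinned 65, at least 300 genes 602, without contralateral libraries 1 and 2 84, left out 0 to 452. Precursor-like (254): DESeq2 160, no filter 623, stricter filter 581, block 538, limma-voom 397, thinned 10, at least 300 genes 516, nuclei with WPRE 159, without contralateral libraries 1 and 2 385, without pair 3 42, left out 22 to 458. Oligodendrocyte-like (291): DESeq2 164, no filter 611, stricter filter 674, block 547, thinned 12, at least 300 genes 616, without contralateral libraries 1 and 2 586, without pair 3 146, left out 86 to 347. Subicular (4): DESeq2 16, totals 7, no filter 61, stricter filter 102, block 23, limma-voom 23, 2 groups 0, thinned 0, at least 1000 genes 0, without contralateral libraries 1 and 2 73, left out 0 to 68.

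Counts for deltaCre-injected against contralateral sums were 0 in CA1-like sums (DESeq2 47, block 163), 0 in CA2-like (no filter 3, block 161), 0 in interneuron-like (DESeq2 1, no filter 28, block 31, 2 groups 9), 0 in oligodendrocyte-like (no filter 1, stricter filter 1, block 1, left out 0 to 1) and 0 in precursor-like sums (DESeq2 3, no filter 20, stricter filter 4, block 32, 2 groups 3, at least 300 genes 2, automatic threshold 1, left out 0 to 1), by edgeR. At an unadjusted p under 0.05 these classes had 769, 232, 472, 475 and 668 genes, and limma-voom called 0 in CA1-like and interneuron-like sums. CA3-like (696): DESeq2 127, no filter 449, block 3389, limma-voom 316, 2 groups 1051, thinned 0, at least 1000 genes 366, resolution 2 1479, left out 4 to 368.

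Interaction counts were 0 in CA1-like sums by edgeR (unadjusted 1552, limma-voom 0, DESeq2 141, block 157, without contralateral libraries 1 and 2 17). Interneuron-like (4): DESeq2 45, totals 22, no filter 346, block 978, limma-voom 0, thinned 8, doublets kept 1, without contralateral libraries 1 and 2 0, without pair 3 171, left out 0 to 191. CA3-like (1): DESeq2 0, relative log expression 2, no filter 2, limma-voom 0, thinned 0, at least 300 genes 3, doublets kept 2, nuclei with WPRE 3, automatic threshold 2, left out 0 to 48. Precursor-like (3): DESeq2 5, no filter 9, stricter filter 5, block 11, at least 300 genes 5, without contralateral libraries 1 and 2 10, without pair 3 0, left out 0 to 5. Oligodendrocyte-like (0 by edgeR, unadjusted 572): DESeq2 3, relative log expression 2, totals 3, no filter 8, stricter filter 13, block 19, at least 300 genes 2, doublets kept 5, automatic threshold 3, without contralateral libraries 1 and 2 52, without pair 3 2, left out 0 to 4. Between injected sides (145): DESeq2 954, totals 786, no filter 225, 2 groups 614, at least 1000 genes 0, resolution 0.5 241, resolution 2 445, without the split sub-clusters 1, without contralateral libraries 1 and 2 850, without pair 3 2590, left out 0 to 296. Between contralateral sides (0 by edgeR, unadjusted 1832, limma-voom 0): DESeq2 17, without pair 3 2327, left out 0 to 5.

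Lists past the threshold with an estimated correlation were 0 in every comparison, except 1 in interneuron-like sums with Cre. Of all lists tested, fry called 12 of 29 in CA1-like sums with Cre (9 higher and 3 lower, against 9 by camera), 9 of 27 in interneuron-like sums with Cre, 3 of 29 between injected sides, 1 of 29 in the interaction of CA1-like sums, and 0 with deltaCre in both classes, between contralateral sides and in the interaction of interneuron-like sums.

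Log2 fold changes of the deleted genes that turned or crossed the threshold, and of other genes that turned, were these. Fos: with Cre -3.43 with the block, -3.41 without pair 3 and -6.80 to -0.17 left out, interaction -3.23 with the block and -6.77 to -0.12 left out, injected sides -7.69 without pair 3, contralateral sides 0.47 without contralateral libraries 1 and 2 and -4.33 without pair 3 and -4.32 to -0.23 left out, deltaCre 0.06 at resolution 0.5 and -1.26 to 0.70 with libraries left out. Fosb: with Cre -0.93 with the block and -3.64 to 1.75 left out, injected sides -4.30 without pair 3 and -4.35 to -0.63 left out, contralateral sides 0.55 and -3.67 under the same omissions and -3.67 to 0.41 left out, deltaCre -1.32 to 1.06, interaction -3.46 to 1.96. Junb: with Cre 0.24 with totals, 0.26 without the split sub-clusters, 0.07 without pair 3 and -3.72 to 3.25 left out, interneuron-like -2.34 to 0.59, injected sides 0.26, 0.29 and -3.61 and -3.68 to 1.00, contralateral sides 0.92 and -4.35 and -4.34 to 1.33, deltaCre -2.12 to 1.22, interaction -0.41 at 1000 genes, -1.39 without contralateral libraries 1 and 2 and -3.08 to 3.92. The ends come from contralateral library 3, Cre-injected library 3 or the deltaCre libraries. Each such omission leaves the other library of its pair in the fit. Nptx2 with Cre was 0.46 with totals, 0.02 thinned, 0.04 at 1000 genes and -0.95 to 0.43 left out. Cdkn1a was -0.11 and Ddit3 -0.22 without the split sub-clusters. Other genes of the texts kept their sign, and among those that shrank by more than 1.5 times with a library left out were, in CA1-like sums with Cre, Ptgs2 (-4.63 to -1.90), Scg2 (-3.99 to -1.41), Bdnf (-3.20 to -0.27), Fosl1 (0.99 to 2.26), Pam (-2.49 to -1.23) and Cdkn1a (1.41 to 2.65), in interneuron-like sums Bdnf (-2.67 to -1.28), Nrn1 (-2.77 to -1.25) and Fosb (-3.37 to -0.68, interaction -3.36 to -0.70), in microglia-like sums Inhba (-6.58 to -3.43) and Plk2 (-4.30 to -2.01), and in CA3-like sums Tac1 (-5.18 to -1.21).

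Differences of shares in points that turned were, with Cre, CA3-like 0.359 at 1000 genes and -1.68 to 1.58 left out, interneuron-like 5.47 at 1000 genes and -2.61 to 0.0574, dentate granule-like -0.184 to 3.40 and subicular -0.556 to 3.17. With deltaCre they were interneuron-like 0.822 at 1000 genes, microglia-like -0.00484 to 0.0400 and precursor-like -0.0367 at 300 genes and -0.0576 to 0.365.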

Other observations

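The list tests in this part were chosen only after the data had been seen, and no hypothesis was tested.

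Nuclei of a cluster led by Nts, which codes for neurotensin, and Dcn, a matrix proteoglycan, were found on the sides without virus. They made up 4.99%, 0.332% and 11.04% of the Cre contralateral libraries and 10.9% and 14.7% of the deltaCre contralateral libraries, and between 0.0143% and 0.103% of the 5 injected libraries. The cluster had under 3 detected markers of any class and entered no comparison. A cluster led by genes of dividing cells and progenitors such as Top2a, a topoisomerase, and Egfr and Pax6 made up 0.670%, 0.186% and 1.52% of the Cre-injected libraries and 0.775%, 0.0316% and 1.36% of their contralateral controls.

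In interneuron-like nuclei with deltaCre, oligodendrocyte markers were higher with a median of 1.97 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 1.2e-05, and adjusted p = 0.453 with an estimated correlation), inhibitory synapse genes lower at -0.29 (0.000509 and 0.331) and interferon genes higher at 0.65 (0.0187 and 0.331). The direction of the 3 lists was the same in CA1-like sums with deltaCre.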
